A study of Mus musculus with 6 samples.

How the data were processed

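RNA was isolated from whole embryos at embryonic day 10.5, and polyadenylated RNA was made into stranded libraries with a KAPA kit, per the labels' protocols. For each of the 6 embryos the authors deposited 2 tables of whole-number counts, one per gene symbol and one per repeat name, with no normalization. Reads were trimmed and aligned to the mm9 mouse genome, and the submitters' processing notes name Trimmomatic, TopHat2, Bowtie2 and HTSeq without versions. The strand setting of the counting, the gene annotation and the repeat annotation are not given in the sources used here. Rows of the deposited count tables that name no gene, such as reads outside genes, ambiguous reads and reads that do not align uniquely, stayed out of library sizes and tests. Reads outside genes made up 9.79% to 18.3% of the alignments per library, and alignments that were not unique 18.2% to 22.6%. Because multiply aligned reads were not counted, young repeats and near-identical genes are represented only by the reads that tell their copies apart.

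Depth was 39395630 to 45782190 alignments per library. The biological coefficient of variation was 12.2% for genes and 27.8% for repeats. The ribosomal RNA gene Rn45s took 2.06% to 8.05% of gene counts. Between any 2 libraries, chi-square values per degree of freedom over genes were 12.4 to 101, far above sampling noise, so the 6 libraries are distinct. Groups and replicate numbers were taken from the sample titles. The same-numbered embryos of the groups did not deviate together, so the numbers were not used as pairs.

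Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests (robust fit, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15), with group as the only term and all 6 libraries in the fit. Of 23366 genes in the files 15075 were kept. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. Standard errors of log2 fold changes are the absolute fold change over the square root of F. CPM values use TMM-scaled library sizes. Where a group had 0 counts in all libraries, the fold is a lower bound from 3 counts over the group. Repeat names were tested in the same way with the scaling of the gene counts, also used for their CPM, so that a general shift of repeats stays visible, and 851 of 1217 were kept. Repeat groups were tested on summed counts. The share of repeat counts was compared by a two-sided exact permutation test, and genes within 10 Mb of the targeted loci by Fisher's exact test.

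Before the data were examined, 32 gene lists were fixed for embryonic tissues, blood, p53 and DNA repair, chromatin, germline and imprinted genes, stress, metabolism and sex-linked markers. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation of 0.01), with an estimated correlation and fry beside it. The list of mitochondrially encoded genes had no member in the files, which left 31. List medians per library use a pseudocount of 0.5 CPM. Chromosome and neighbourhood came from a GRCm38 reference matched by symbol for 15018 of the tested genes, while the files use mm9, so no coordinates are given.

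The genes named in the text were chosen by a rule set before the data were examined. It took H3f3a, H3f3b and Trp53, and the 8 higher and 8 lower called genes with the largest fold, a mean of at least 2 CPM and groups fully apart, outside Xist, Tsix and Y-linked genes. It also took the 5 higher and 5 lower with the smallest p under the same conditions, and up to 4 members of each list with the smallest p, called or not. For repeats it took the 5 higher and 5 lower called ones, of which there were none, and 8 fixed names, of which the L1Md_A and L1Md_T entries of the files stand for the A and T subfamilies of young LINE-1. Genes outside the rule are said to be chosen after their values were seen, except those that only complete a count: the 4 members of the macrophage list that were not called, the called genes near the targeted loci, Il3ra, and ETnERV3-int and RMER17A-int. Leukocyte genes were assigned by hand after the values were seen.

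Alternatives set before the data were examined were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom, other filters on low counts, other thresholds, the replicate number as a block, each library left out in turn, 2 knockout libraries whose files share a code summed, the erythroid list left out, and a fit without robust priors. For repeats they were TMM on the repeat counts, library totals, no filter, and simple repeats left out. Those added after seeing the data left out ribosomal RNA genes, took the share of reads outside genes as a covariate, or left out 2 knockouts at once. Near the loci they used a 2 Mb window, left out leukocyte genes, or left out each library in turn, the last also for chromosomes. Another left structural RNA out of the repeat share. The closing section gives their effect. Of the knockouts, only knockout 2 had a share of reads outside genes within the range of the controls. Group differences with that covariate therefore rest mostly on knockout 2.

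The methods were tested on simulated counts for the real genes with known changes. For 15075 genes, edgeR recovered 60% of those changed 1.5-fold, 84% at 2-fold and 100% at 4-fold and 8-fold, and 5.49% of calls were unchanged genes. For 851 repeats the shares were 18%, 58%, 96% and 98%, with 3.57% false calls. Among 25 simulated lists, camera called all 5 whose members were all raised 1.5-fold and 0 of 20 unchanged ones. Smaller shifts of lists were not simulated. Genes and repeats were simulated independently of each other, so this does not test camera on lists whose genes vary together between embryos. The shares of false calls for genes and repeats do not cover such joint variation either.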

Results

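Polyadenylated RNA was sequenced from 6 whole mouse embryos at E10.5, with 3 embryos in each of 2 groups. Histone H3.3 is the variant of histone H3 that is deposited independently of DNA replication, and H3f3a and H3f3b both encode it. Knockout embryos carried a null and a floxed allele of each gene, control embryos a wild-type and a floxed allele, and both groups carried Sox2-Cre, a recombinase transgene active in the epiblast. All embryos also lacked Trp53, the gene of the tumour suppressor p53, on a mixed C57BL/6, CD1 and 129 background. The labels do not say whether embryos of the groups were littermates or how RNA was pooled, so p-values measure only the spread between these samples. The files held 24952853 to 30461689 counts in genes per library, with 29562000 ± 1546900 in controls and 26869000 ± 1660100 in knockouts (SD, n = 3 each). A second set of files held 2661391 to 4600118 counts per library in families of repeated sequence. The Y-linked gene Ddx3y was expressed in both groups, at 86.4 ± 8.03 CPM (counts scaled to library size) in controls and 99.0 ± 1.74 CPM in knockouts (n = 3), and Xist gave 8 to 26 counts per library.

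H3f3a and H3f3b were both lower in the knockouts, H3f3a by far the more. H3f3a fell from 349 ± 15.4 CPM in controls to 67.7 ± 2.91 CPM in knockouts (SD, n = 3), with 9851, 10775 and 9685 counts in the controls against 1818, 1744 and 1996 in the knockouts. This was 5.16-fold lower, a log2 fold change of -2.37 ± 0.08 (SE), at an edgeR adjusted p of 1.5e-06. H3f3b fell from 691 ± 31.5 to 455 ± 56.8 CPM (n = 3), with 19717, 21379 and 18942 counts against 12164, 13626 and 11431. Its log2 fold change was -0.60 ± 0.10 and its edgeR adjusted p was 0.0257. Trp53, null in both groups, had 2.75 ± 0.49 CPM in controls and 4.52 ± 1.27 CPM in knockouts (n = 3), from 64, 87 and 88 against 148, 86 and 136 counts, with an edgeR adjusted p of 0.169. The counts pool all exons of a gene, and the labels do not say which exons the null and floxed alleles lack, so the remaining counts do not measure functional transcript. The call of H3f3b was lost without control 1 (edgeR adjusted p = 0.14), control 2 (0.113), control 3 (0.0617) or knockout 3 (0.0938), while H3f3a was called with any library left out.

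**Figure D1:**
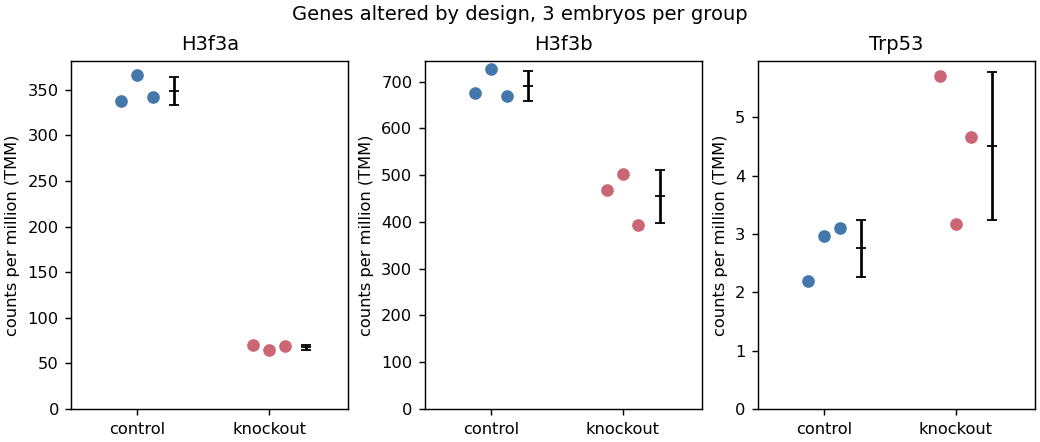
CPM of H3f3a, H3f3b and Trp53 in each of the 6 libraries, with the mean and SD of each group of 3 beside the points. The knockout libraries of H3f3a lie near 67.7 CPM against 349 CPM in the controls, and those of H3f3b near 455 against 691 CPM.

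The comparison of all genes asked which transcripts differ in p53-null embryos that also lack a wild-type allele of H3f3a and H3f3b. The controls carried Sox2-Cre as well, so their floxed alleles were open to deletion. Folds are therefore not measured against embryos with intact H3.3 genes. The genes that fell furthest belonged to macrophages: Csf1r, the receptor for colony stimulating factor 1, fell 66.1-fold, and the fractalkine receptor Cx3cr1 fell 109-fold. Csf2rb and Csf2rb2, which encode beta chains of the receptors for interleukin 3, interleukin 5 and GM-CSF, rose most among the called genes with a mean of at least 2 CPM. Of 15075 tested genes, 2896 had an unadjusted p under 0.05, and 83 were higher and 144 lower in the knockouts by edgeR at an adjusted p under 0.05, which is 1.51% of those tested. Of the higher genes, 32 rose at least 2-fold and 11 at least 4-fold, with a median log2 fold change of 0.91. Among the lower genes, 109 fell at least 2-fold and 80 at least 4-fold. Judged by hand after the values were seen, 91 of the 144 lower genes are used mainly by leukocytes, as are 71 of the 80 that fell at least 4-fold, and the other 53 lower genes had a median log2 fold change of -0.79. All 227 called genes had the groups of 3 fully apart, as did 24.1% of all tested genes, where chance gives 10%. The numbers of higher and lower genes depended on the embryos included, with 10 and 60 without control 1, 7 and 53 without control 2, 32 and 88 without control 3, 95 and 138 without knockout 1, 1159 and 504 without knockout 2, and 18 and 83 without knockout 3.

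**Figure D2:**
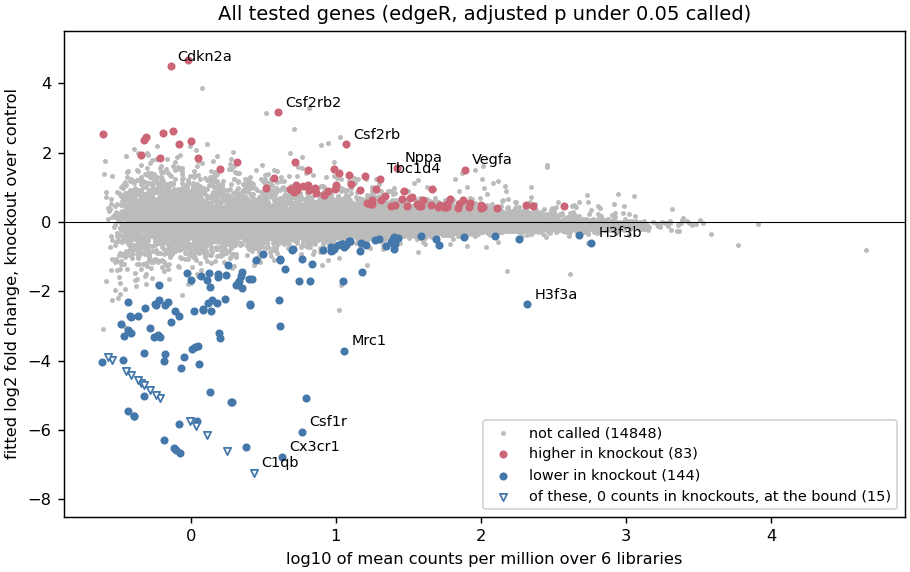
Fitted log2 fold change (knockout over control) of 15075 tested genes against the log10 of their mean CPM, with 83 genes called higher in red and 144 called lower in blue. Open triangles mark 15 genes with 0 counts in all knockouts, drawn at the bound set by 3 counts over the group, such as C1qb at 150-fold.

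Macrophage transcripts were far lower in all 3 knockout embryos. Cx3cr1 went from 8.42 ± 0.335 to 0.0737 ± 0.0396 CPM (SD, n = 3), and Csf1r from 11.5 ± 1.35 to 0.17 ± 0.10 CPM. The mannose receptor Mrc1 fell from 21.3 ± 2.67 to 1.63 ± 0.451 CPM, a log2 fold change of -3.71 ± 0.20 (SE). The complement gene C1qb had 179, 168 and 130 counts in the controls and 0 in every knockout, at least 150-fold lower at 3 counts over the group. Of 20 tested genes in the list for macrophages and other white blood cells, 16 were lower by edgeR, 19 when adjusted over the list alone, and none was higher. The 4 not called were Cd68 at -0.06, Pf4, a platelet gene, at -0.93, Aif1 at -3.04 and the granule protease gene Prtn3. All 20 folds were below 0, with a median log2 fold change of -3.53 whether or not the genes without counts were set at their bounds, and the camera adjusted p was 6.18e-30. The list was also called with an estimated correlation (adjusted p = 0.0349) and by fry (adjusted p = 8.9e-05). Without single libraries its median lay between -3.85 and -3.33 and 12 to 18 members were called.

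**Figure D3:**
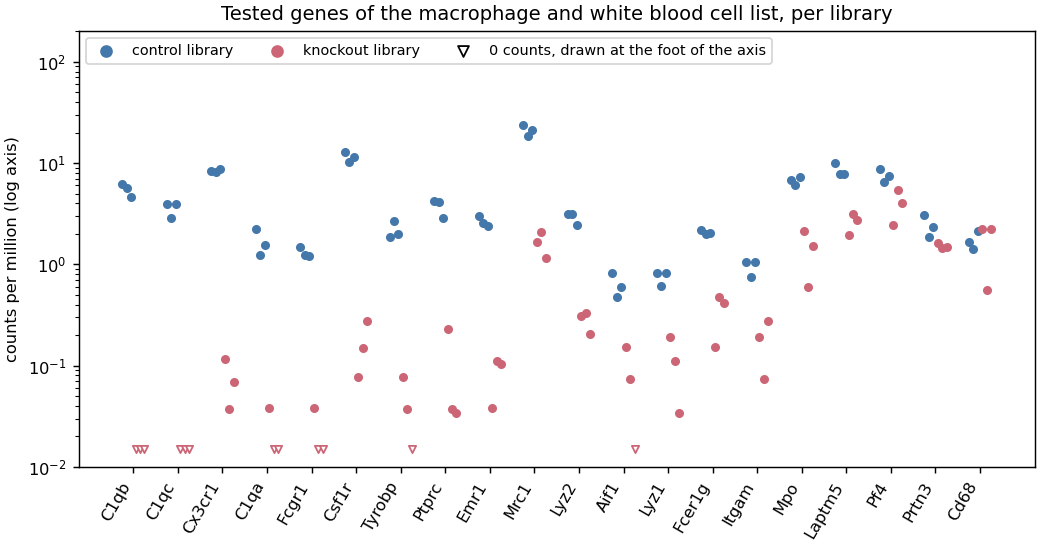
CPM, on a log axis, of the 20 tested genes of the macrophage and white blood cell list in each of the 6 libraries, with open triangles at the foot of the axis for 0 counts. Control libraries of Csf1r average 11.5 CPM and knockout libraries 0.166 CPM, while those of Cd68 overlap.

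Further macrophage genes outside that list were among the largest decreases. Mpeg1, the perforin-like gene of macrophages, fell from 4.79 ± 0.671 to 0.0489 ± 0.0217 CPM (SD, n = 3), a log2 fold change of -6.50 ± 0.34 (SE), and had 1, 2 and 1 counts in the knockouts. F13a1, the coagulation factor XIII A subunit that tissue macrophages make, fell from 12.1 ± 1.49 to 0.36 ± 0.13 CPM. Nckap1l, a regulator of actin in blood cells, and Cyth4 fell less, by 3.01 and by 2.38 on the log2 scale. edgeR adjusted p-values of these 4 genes ran from 1.52e-05 for F13a1 to 0.00083 for Cyth4, and each was called with any library left out.

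Erythroid genes, of the other main blood lineage at this stage, gave no calls. None of 25 tested erythroid genes was called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05, and their median log2 fold change was 0.09, with a camera adjusted p of 0.664. The embryos differed, with list medians against the control mean of 0.31, -0.34 and 0.24 in knockouts 1, 2 and 3. Camera called the list as higher without knockout 2 (0.27, adjusted p = 0.00275), and its median was under 0.01 without knockout 1 or knockout 3. With the share of reads outside genes as a covariate, a fit that rests mostly on knockout 2, camera called it as lower (-0.31, adjusted p = 2.32e-08). The 4 with the smallest p were Icam4 at -0.62, Nfe2 at 0.47, Trim10 at 0.43 and Gfi1b at 0.46, none with an edgeR adjusted p under 0.249.

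Endothelial genes were slightly higher as a group, with 20 of 24 folds above 0. Kdr, the receptor for the vascular growth factor made by Vegfa, rose from 88.4 ± 2.93 to 120 ± 8.72 CPM (SD, n = 3), a log2 fold change of 0.44 ± 0.08 (SE) with an edgeR adjusted p of 0.0302. Lyve1, a marker of lymphatic endothelium that fetal macrophages also make, fell from 2.22 ± 0.356 to 0.432 ± 0.175 CPM, at -2.34 ± 0.32 and an edgeR adjusted p of 0.00913. Of 24 tested members 1 was higher and 1 lower by edgeR, 6 and 1 when adjusted over the list alone. Among those not called over all genes, Tie1 had a log2 fold change of 0.41 and Flt1 of 0.90. The median was 0.27 (camera adjusted p = 0.00502), but the adjusted p was 0.824 with an estimated correlation. With the share of reads outside genes as a covariate the median was 0.48 (camera adjusted p = 2.21e-08), a fit that rests mostly on knockout 2. Against the control mean, knockouts 1, 2 and 3 were at 0.04, 0.50 and 0.18, and control 1 at 0.07. Without knockout 2 the list median was 0.09 and the camera adjusted p 0.184. The call of Kdr was lost without control 1, control 2, control 3 or knockout 3 (edgeR adjusted p up to 0.188), and that of Lyve1 without control 1 or control 2 (up to 0.0601).

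Genes of the response to low oxygen and of glycolysis read higher, by very different amounts in the 3 knockout embryos. Vegfa, the vascular endothelial growth factor gene, rose from 40.2 ± 8.22 to 114 ± 25.5 CPM (SD, n = 3), a log2 fold change of 1.51 ± 0.19 (SE) with an edgeR adjusted p of 0.00699. Vegfa was the only called gene of the 31 tested, also when adjusted over the list alone. All 31 folds were above 0, with a median of 0.77 and a camera adjusted p of 1.66e-07, but the adjusted p was 0.824 with an estimated correlation and 0.42 by fry. The median over the list against the control mean was 0.09 in knockout 1, 1.40 in knockout 2 and 0.41 in knockout 3. Adm, the adrenomedullin gene, had 40, 45 and 36 counts in the controls and 87, 499 and 145 in the knockouts, and Pfkfb3, a regulator of glycolysis, had 1159, 1068 and 1177 against 1403, 4028 and 2204. Without knockout 2 the list median was 0.24 (camera adjusted p = 4.39e-05), and without control 2 the edgeR adjusted p of Vegfa was 0.0665. With the share of reads outside genes as a covariate the list median was 1.27 (camera adjusted p = 1.66e-21). Of the knockouts, only knockout 2 lay within the range of that share in the controls, so this fit rests mostly on knockout 2.

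Nuclear genes of oxidative phosphorylation were slightly lower. Of 75 tested members 69 had folds below 0, among them Uqcrb at -0.33, Ndufs8 at -0.34 and Ndufb10 at -0.32, none called by edgeR. Cox6b2, the testis form of a cytochrome c oxidase subunit, was the only called member over all genes and over the list alone, and rose from 3.71 ± 0.683 to 7.11 ± 0.205 CPM (SD, n = 3) with an edgeR adjusted p of 0.0311. The median log2 fold change was -0.15 (camera adjusted p = 7.23e-05), and the adjusted p was 0.824 with an estimated correlation. Knockouts 1 and 3, in which 18.3% and 18.0% of alignments lay outside genes, had list medians of -0.27 and -0.24, while knockout 2, with 10.6% outside genes, had 0.05. Short genes moved in the same way, with medians of -0.128, -0.113 and 0.028 in knockouts 1, 3 and 2 for the fifth of genes with the shortest exonic length, and the list has a median exonic length of 1001 bases. With the share of reads outside genes as a covariate the list median was 0.031 and camera no longer called it (adjusted p = 0.0879). The list median was -0.28 without knockout 2, -0.08 without knockout 1, -0.10 without knockout 3 and -0.09 without control 2, and the call of Cox6b2 was lost without control 1, control 2, knockout 1 or knockout 3 (edgeR adjusted p up to 0.163).

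Lists of differentiating neurons and of the cell cycle had medians slightly below 0, with embryos of the groups overlapping. Nhlh1, a transcription factor of newly formed neurons, fell from 29.8 ± 3.3 to 19.7 ± 1.29 CPM (SD, n = 3), a log2 fold change of -0.60 ± 0.11 (SE) with an edgeR adjusted p of 0.0333. Tubb3, a neuronal tubulin, was at -0.44 with an edgeR adjusted p of 0.102, and Neurod4 and Elavl4 at -0.41 and -0.31. Nhlh1 was the only one of 32 neuronal genes called, also over the list alone, and 25 folds were below 0. The neuronal median was -0.23 (camera adjusted p = 0.00502, but 0.824 with an estimated correlation). Per library it was 0.078, -0.239 and 0.175 in the controls and -0.027, -0.409 and -0.235 in the knockouts, against the control mean. None of the 31 genes of replication and mitosis was called by edgeR, over all genes or over the list alone, with 5 at an unadjusted p under 0.05, 1 called lower by DESeq2 and none by limma-voom. The lowest p among them belonged to Cenpf, a kinetochore gene, at -0.28, and the median was -0.13 (camera adjusted p = 0.00517). Its camera adjusted p was 0.824 with an estimated correlation. Per library the cell cycle median was -0.034, 0.141 and -0.099 in the controls and -0.134, -0.085 and -0.123 in the knockouts. With the share of reads outside genes as a covariate, the neuronal median was -0.42 (camera adjusted p = 5.51e-06) and the cell cycle list was no longer called (-0.08, 0.227). That fit rests mostly on knockout 2. The neuronal list lost its call without control 3 (camera adjusted p = 0.149) or knockout 2 (0.128), and its median was -0.15 without control 3, -0.37 without control 2 and -0.35 without knockout 1. The cell cycle list lost its call without control 2 (median -0.05, camera adjusted p = 0.223), and Nhlh1 was lost without control 1, control 3, knockout 1 or knockout 3 (edgeR adjusted p up to 0.19).

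**Figure D4:**
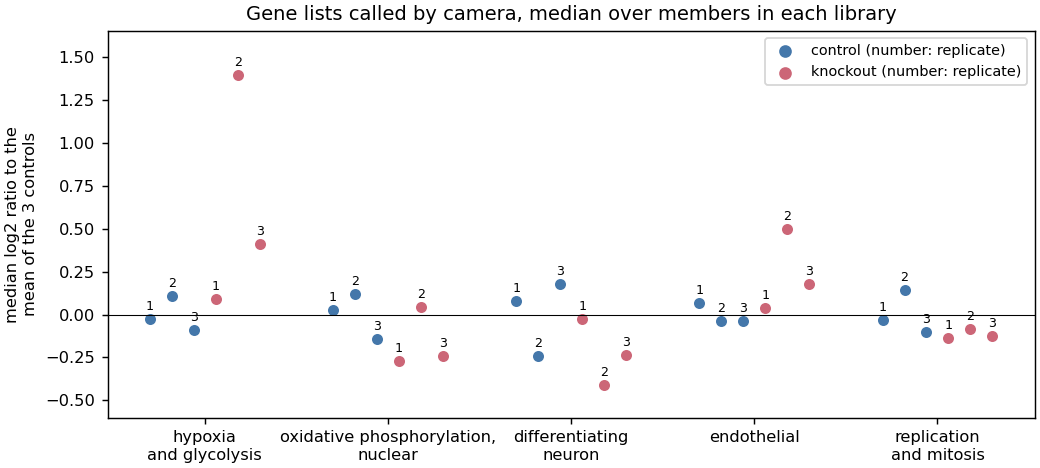
Median log2 ratio to the control mean over the members of 5 gene lists in each library, with replicate numbers beside the points. The hypoxia and glycolysis list lies at 0.09, 1.40 and 0.41 in knockouts 1, 2 and 3.

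Among called genes with a mean of at least 2 CPM and the groups apart, those with the largest increases or smallest p varied in function. Csf2rb2 rose from 0.809 ± 0.263 to 7.24 ± 3.16 CPM (SD, n = 3), 8.94-fold, and Csf2rb from 4.07 ± 0.948 to 19.3 ± 4.21 CPM, 4.75-fold. These neighbouring genes are near-identical, so how reads were divided between them is uncertain. Nppa, the atrial natriuretic peptide of heart muscle, rose from 13.5 ± 3.03 to 39.7 ± 11.3 CPM, and Tbc1d4, a regulator of glucose transporter traffic, from 12 ± 0.962 to 28.4 ± 2.66 CPM. The others that the naming rule picked were Atp10d at a log2 fold change of 1.41, the pseudogene Nlrp5-ps at 1.74, the gut and brain peptide gene Cck at 1.72, the peptide transporter gene Slc15a2 at 1.52 and 1700001L05Rik at 1.51. edgeR adjusted p-values ran from 0.00083 for Tbc1d4 to 0.043 for Cck. Only Csf2rb and Tbc1d4 were called with any library left out. Csf2rb2 (edgeR adjusted p = 0.0502) and Atp10d (0.0634) were lost without control 2, Nppa without control 2 or control 3 (up to 0.0804), Nlrp5-ps without control 1 or control 2 (up to 0.0934), and Cck, Slc15a2 and 1700001L05Rik without control 1, control 2, control 3 or knockout 3 (up to 0.203).

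Targets of p53 and genes of DNA repair were compared because the series concerns the integrity of the genome. All embryos lacked Trp53, so the list of p53 targets cannot show whether the loss of H3.3 brings on a response that needs p53. Cdkn2a, which encodes the inhibitor p16 and the p53 activator ARF and is not itself a classic p53 target, rose from 0.0577 ± 0.0203 to 1.40 ± 0.985 CPM (SD, n = 3), from 1, 2 and 2 to 33, 66 and 14 counts, with an edgeR adjusted p of 0.0248. Trp53inp1, a stress-induced p53 target, fell from 62.9 ± 3.66 to 39.8 ± 8.08 CPM with an edgeR adjusted p of 0.0468. Perp at -0.60 and Ddb2 at 0.78 were not called. Among 32 tested genes of the p53 list 1 was higher and 1 lower, and 3 and 3 when adjusted over the list alone. Its median was -0.06 and its mean 0.06, with a camera adjusted p of 0.542. Members moved both ways, with 9 at an unadjusted p under 0.05 and 4 called by DESeq2. The mixed test of fry, which counts changes in either direction, gave this list an unadjusted p of 0.000205. Mdc1, which recruits repair factors to DNA breaks, rose from 168 ± 5.76 to 238 ± 16.4 CPM, at 0.50 ± 0.08 (SE) and an edgeR adjusted p of 0.0142. It was the only called gene of 29 in the list of DNA damage checkpoint and repair, where 1 was higher and 1 lower over the list alone, with a median of -0.0092, a mean of 0.02 and a camera adjusted p of 0.983. At an unadjusted p under 0.05 the repair list held 5 genes, and its mixed fry p, unadjusted, was 0.00744. Cdkn2a was lost without control 1, control 2 or control 3 (edgeR adjusted p up to 0.153), Trp53inp1 without control 1, control 2, control 3 or knockout 3 (up to 0.249), and Mdc1 without control 1, control 2 or knockout 3 (up to 0.119).

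Histone and chromatin lists did not pass the test with group as the only term and all 6 libraries. Among 35 tested replication-dependent histone genes 25 had folds below 0 and none was called by edgeR, also over the list alone, nor by DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05, a median of -0.26 and a camera adjusted p of 0.0806. Camera called this list as lower without control 2 (-0.38, adjusted p = 0.00452), control 3 (-0.33, 0.0318), knockout 1 (-0.27, 0.0381) or knockout 2 (-0.31, 0.0481), while its median was -0.04 without control 1 and -0.07 without knockout 3. Many of these genes are near-identical copies and their transcripts lack poly(A) tails, so their counts are uncertain. Hist1h2ak, for example, had 328, 790 and 440 counts in controls and 190, 36 and 23 in knockouts, with an edgeR adjusted p of 0.189. The 21 histone variants and H3 chaperones had a median of -0.08, a mean of 0.01 and no gene called by edgeR, 4 at an unadjusted p under 0.05 and 2 called by DESeq2, with H1f0 at 0.44 and the centromeric chaperone Hjurp at 0.69. The 31 genes of centromeres, telomeres and heterochromatin had a median of 0.02 and none called by edgeR or DESeq2, 5 at an unadjusted p under 0.05, with Cbx1 at -0.23 and Kdm4b at 0.33. Camera adjusted p-values of the last 2 lists were 0.583 and 0.622, and limma-voom called no member of either. Their mixed fry p-values, unadjusted, were 0.0783 and 0.0262.

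Few genes of body patterning and tissue lineages were called by edgeR. The Hox list had 39 tested genes, a median of 0.13 and no gene called by edgeR, and the lists of neural progenitors (median 0.0019), neural crest (0.0019, mean -0.03), presomitic mesoderm and tail bud (0.23), somite and skeletal muscle (-0.14), limb bud (0.07), mesenchyme (0.05) and eye (-0.15) had none either. At an unadjusted p under 0.05 these 8 lists held 4, 10, 3, 3, 4, 5, 7 and 3 genes in that order, and DESeq2 called 3 neural progenitor, 2 tail bud, 4 mesenchyme and 1 eye gene, limma-voom none. Camera adjusted p-values of these lists ran from 0.0816 for somites to 0.983 for neural crest. The mixed test of fry, which counts changes in either direction, gave unadjusted p-values of 2.66e-05 for neural progenitors, 0.000655 for limb bud and 0.0127 for somites. For the others of these lists the mixed fry p was at least 0.0514. Camera called the somite list without control 2 (-0.12, adjusted p = 0.0303) or knockout 1 (-0.08, 0.0381), and the eye list without control 2 (-0.19, 0.00452), knockout 1 (-0.23, 0.0331) or knockout 3 (-0.18, 0.0437). Adjusted over the list alone, 1 gene was lower among neural progenitors and 2 were higher among tail bud genes. Neurog2, a proneural factor, was at -0.47, and the mesoderm genes T and Tbx6 at 1.11 and 1.6, with edgeR adjusted p-values of 0.0675, 0.101 and 0.106. In the heart list Nppa was the 1 called gene of 23, 4 over the list alone, with Myh7 at 0.49 and a median of 0.20 (camera adjusted p = 0.101, but 0.0381 without knockout 1 and 0.0437 without knockout 3, at medians of 0.22 and 0.20). Ttr, the transthyretin gene of yolk sac and liver, fell from 10.2 ± 2.14 to 3.16 ± 0.894 CPM (SD, n = 3) with an edgeR adjusted p of 0.00886. It was the 1 called gene of 27 hepatoblast and yolk sac genes, where 2 were lower over the list alone, with a median of -0.18 (camera adjusted p = 0.0806), and the call of Ttr was lost without control 1 (edgeR adjusted p = 0.0528). The call of Nppa was lost without control 2 or control 3 (up to 0.0804). Mixed fry p-values, unadjusted, were 0.00306 for the heart list and 0.0596 for the hepatoblast and yolk sac list. The hepatoblast and yolk sac list was called by camera without control 3 (-0.41, adjusted p = 0.0104), knockout 1 (-0.31, 0.0015) or knockout 2 (-0.35, 0.0267), and its median was -0.03 without knockout 3.

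Germline, imprinted and stress genes gave few calls. Sycp2, a component of the meiotic synaptonemal complex, rose from 0.185 ± 0.102 to 1.10 ± 0.287 CPM (SD, n = 3), at a log2 fold change of 2.55 ± 0.44 (SE) and an edgeR adjusted p of 0.0275. It was the 1 called gene of 9 in the germline and two-cell list, with 2 over the list alone, a median of 0.25 and a camera adjusted p of 0.109 (0.28 and 0.0423 without knockout 1). Nnat, a paternally expressed imprinted gene, fell from 538 ± 23.9 to 411 ± 20 CPM with an edgeR adjusted p of 0.0493. Of 40 imprinted genes it was the 1 called, 7 higher and 3 lower over the list alone, and the median was -0.02 and the mean 0.12 (camera adjusted p = 0.867). Mixed fry p-values, unadjusted, were 0.00728 for the imprinted and 0.00738 for the germline list. Igf2r at 0.46 and its antisense transcript Airn at 1.02 had edgeR adjusted p-values of 0.0504 and 0.0554, and their counts are uncertain because the strand setting of the counting is not given. Sycp2 and Nnat were lost without any single library except knockout 2 (edgeR adjusted p up to 0.119 and 0.297).

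The remaining lists had no gene called by edgeR over all genes. These were pluripotency (11 tested, median 0.23), trophoblast and placenta (9, 0.05, mean -0.09), interferon response (18, -0.03), integrated stress response (26, 0.06), immediate early and heat shock genes (22, 0.11), ribosomal proteins (82, -0.03) and sex-linked markers (6, 0.24). At an unadjusted p under 0.05 they held 4, 5, 4, 3, 5, 0 and 1 genes in that order, DESeq2 called 1 gene in each of the pluripotency, placental, stress response and immediate early lists, and limma-voom none. Their camera adjusted p-values ran from 0.0806 to 0.867. In the same order, mixed fry p-values, unadjusted, were 0.00166, 0.00255, 0.00634, 0.273, 0.00096, 0.731 and 0.127. Ribosomal protein genes were called as lower by camera without knockout 2 (-0.23, adjusted p = 4.33e-08) or control 3 (-0.10, 0.0114), had a median of 0.11 without knockout 1, and have a median exonic length of 977 bases. Camera also called the stress response list without knockout 1 (0.13, adjusted p = 0.0258), the immediate early list without knockout 1 (0.10, 0.0269) or knockout 3 (0.20, 0.0389), and the sex-linked list without control 3 (0.33, 0.0318). Adjusted over the list alone, 1 pluripotency gene, 3 immediate early or heat shock genes, 1 placental and 1 interferon gene were higher, and 1 placental and 2 interferon genes lower. Egr1, an immediate early gene, was at 0.68 with an edgeR adjusted p of 0.0628, and Vldlr, of the stress response list, was at 1.12 with 790, 1902 and 1208 counts in the knockouts against 616, 623 and 659. In the placental list, Slc16a3, a lactate exporter, had 1681, 6294 and 3109 counts against 1285, 1581 and 1297. Of the 31 tested lists, camera called 6, and 1 of them, that of macrophages, was also called with an estimated correlation and by fry.

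Repeated sequence was compared because H3.3 is placed at heterochromatic repeats. Counts of the ETn and MusD retroviral family were 468 ± 71.8 CPM in controls and 712 ± 86.7 CPM in knockouts (SD, n = 3), a log2 fold change of 0.60 ± 0.16 (SE), with an edgeR adjusted p of 0.139. IAP elements, an active retroviral family of the mouse, were at 197 ± 29.9 and 215 ± 38.2 CPM, and satellites at 2718 ± 125 and 2647 ± 45.1 CPM. Most satellite counts came from MMSAT4, at 1789 and 1718 CPM, so the group says little of the major satellite, which had too few counts for a test. None of 851 tested repeat names was called by edgeR, with 106 at an unadjusted p under 0.05 and a smallest adjusted p of 0.28, and DESeq2 called 2 as higher, ETnERV3-int at 1.17 and RMER17A-int at 1.25. None of 15 repeat groups was called by edgeR either, with ETn and MusD the 1 at an unadjusted p under 0.05, although camera over repeat names called that group (adjusted p = 0.00375) and older LINE-1 elements (0.0468). Folds were above 0 for 776 repeats (91.2%), with a median of 0.48, when repeats were scaled by the gene counts, and for 53.6% with a median of 0.02 when scaled by their own counts. The share above 0 moved with reads outside genes, since the median repeat was at 0.62 in knockouts 1 and 3, with 18.3% and 18.0% of alignments outside genes, and at -0.07 in knockout 2, with 10.6%. Without knockout 2, edgeR called 542 repeats higher, 2 lower and 10 groups.

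**Figure D5:**
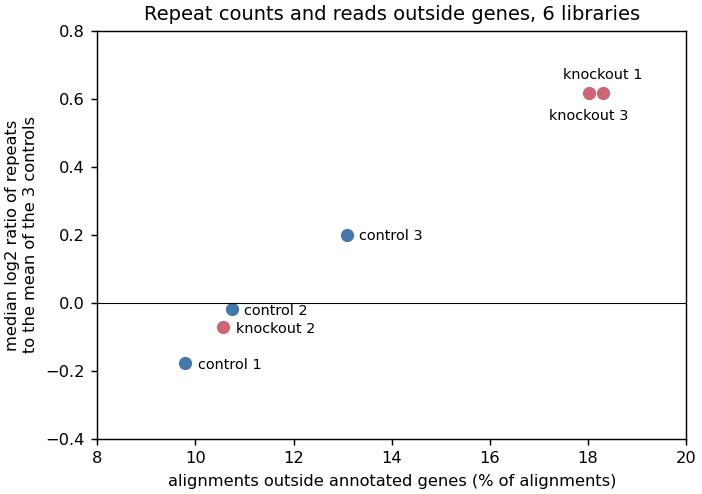
Median log2 ratio of 851 repeats to the control mean against the percent of alignments outside annotated genes, for 6 libraries. Knockouts 1 and 3 lie at 0.62 with 18.3% and 18.0% outside genes, and knockout 2 lies at -0.07 with 10.6%.

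Individual repeats named beforehand went both ways and none was called. The satellite MMSAT4 was at -0.06 ± 0.17 (SE) on the log2 scale, the IAP internal sequence IAPEz-int at -0.04 ± 0.21, and MERVL-int, expressed in the two-cell embryo, at 0.51 ± 0.31. The LINE-1 elements L1Md_A and L1Md_T were at 0.50 ± 0.26 and -0.46 ± 0.24, and B2_Mm1a at 0.47 ± 0.26. None had an edgeR adjusted p under 0.28. The major satellite GSAT_MM gave 6 to 14 counts per library and SYNREP_MM 0 to 2 counts, too few for a test. B1 elements were at 6601 ± 1025 and 8916 ± 2859 CPM, and B2 elements at 1243 ± 214 and 1835 ± 536 CPM (SD, n = 3), with edgeR adjusted p-values of 0.321 for both.

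Repeat counts in all amounted to 12.5 ± 2.27% of gene counts in controls and 10.6 ± 1.59% in knockouts (SD, n = 3), with a two-sided exact permutation p of 0.3, where 3 against 3 allows 0.1 at the lowest. The difference of -1.87 points was -0.57 without control 1 and -2.79 without knockout 1. Ribosomal RNA repeats made up 8.38 ± 2.76% and 5.19 ± 1.48% of gene counts (exact permutation p = 0.1). With ribosomal, transfer and small nuclear RNA left out, repeats amounted to 4.10 ± 0.580% in controls and 5.41 ± 1.36% in knockouts (exact permutation p = 0.3). Floors throughout cover counting error only, and the interval of the odds ratio below takes genes as independent.

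Genes near the targeted loci were examined because a null allele brings its flanking chromosome with it. Within 10 Mb of H3f3a on chromosome 1 or H3f3b on chromosome 11, 11 of 336 tested genes were called, against 213 of 14680 elsewhere, an odds ratio of 2.30 (95% interval 1.12 to 4.25, Fisher's exact test p = 0.0183). They were Cox20, needed for assembly of cytochrome c oxidase, the nucleotidase gene Nt5c, Mettl23, the Wnt inhibitor Notum, Nhlh1, and the leukocyte genes Fcer1g, Fcgr3, Arhgap30, Milr1, Ifi202b and AI607873. Notum was higher at a log2 fold change of 0.86, and the others lower, with Cox20 at -0.73 and Nt5c at -0.66. Fisher's test and its interval take genes as independent, while the leukocyte genes among these fell together in the same embryos. The odds ratio was 1.31 within 5 Mb (Fisher's exact test p = 0.555) and 1.76 within 20 Mb (0.0417). Without leukocyte genes it was 1.74 within 10 Mb, which left 5 of 330 (0.223), and 2.23 within 5 Mb (0.114). The leukocyte genes left out were all called ones, so these values cannot tell whether calls near the loci depend on leukocyte genes. With all genes within 10 Mb, Fisher's exact p was above 0.05 when any 1 library was left out. It ran from 0.0504 without control 3 to 0.725 without knockout 2, with 0.0682 for control 1, 0.144 for control 2, 0.112 for knockout 1 and 0.0763 for knockout 3. No chromosome was called by camera among 21 tested, with chromosomes 17 and Y at an unadjusted p of 0.0439 and 0.0277 and medians of 0.05 and 0.24.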

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

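The test of ribosomal RNA and of reads outside genes was set before its result was seen, and the fits that took those reads as a covariate or left out knockouts 1 and 3 were chosen afterwards. In knockouts 1 and 3, 18.3% and 18.0% of alignments lay outside annotated genes, above the 9.79% to 13.1% of the controls, while knockout 2 had 10.6%. These reads belong to no gene and entered no comparison of genes. Most repeats read higher in the knockouts with them, at 91.2% of 851 repeats with a fold above 0.

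A general rise of repeat transcription in every knockout is not what the libraries show, since the median repeat in knockout 2 was at -0.072 on the log2 scale against 0.62 in both others. Not every repeat group followed the median. ETn and MusD stood at 745, 614 and 778 CPM in knockouts 1, 2 and 3 against 403, 545 and 457 CPM in controls. edgeR did not call that group (adjusted p = 0.139). Whether the share of ribosomal RNA plays a part stays open, because leaving it out of genes and repeats, with 91.4% of repeats above 0 afterwards, moved the median only from 0.482 to 0.483 and so tested nothing. Reads from introns, unannotated transcripts or genomic DNA may account for the shift, which fell to a median of -0.05 with the share of reads outside genes as a covariate. Repeat reads outside genes are part of that share, so the covariate would also take out a rise of repeats from another cause. The fit therefore cannot tell these apart. Whether the reads outside genes differ through the knockout or through library preparation stays open. Their share was above every control in 2 of 3 knockouts. Splits of the 6 libraries into 3 and 3 number 10, which cannot give a share under 0.05: the real split called 0 repeats and 0 repeat groups, and the split of control 1, control 2 and knockout 2 against the rest called 538 repeats and 10 groups, which points to a structure of the samples that follows reads outside genes.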

How the results depend on the processing

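The covariate of reads outside genes, the fits without ribosomal RNA or without several knockouts, the 2 Mb window, the omission of leukocyte genes or structural RNA, and leaving out libraries for neighbourhood and chromosomes were chosen after the data were seen. Of the results of 156 named genes under the alternatives, 2802 stayed on the same side of the threshold, 173 passed it newly, 114 no longer passed, and 0 changed sign with a call in either fit. For lists these numbers were 354, 31, 15 and 3, and lists called in neither fit also changed sign. Scalings moved the median of all genes by at most 0.06, and the macrophage list was called in every alternative run with camera or fry, with medians from -3.85 to -3.29. The depth of 24952853 to 30461689 gene counts limits genes of few counts. Where no cause is given, the cause was not tested.

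Against 83 higher and 144 lower genes, DESeq2 called 441 and 328, limma-voom 52 higher, no filter on low counts 144 higher, and a mean of at least 2 CPM, which tests fewer genes, 25 and 32. Summing the 2 knockouts with a shared file code gave 270 higher, the covariate 437 and 311, knockout 3 alone 411 higher (1 library, so that the spread comes from the controls only), a log2 fold of at least 1 gave 32 higher, and an adjusted p under 0.1 gave 272 and 256. Without single libraries the higher genes ranged from 7 to 1159 and the lower genes from 53 to 504. Of the 227 called genes, DESeq2 kept 226, limma-voom 172, the covariate 213 and the least inclusive leave-one-out fit, without control 2, kept 56. H3f3b stood at -0.60 (edgeR adjusted p = 0.0509) with a mean of at least 2 CPM and between -0.68 and -0.51 without single libraries, with edgeR adjusted p-values up to 0.14.

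With the replicate number as a block, 333 genes were higher and 256 lower, and camera called 11 lists, those called without it and the replication-dependent histone (adjusted p = 0.0397), hepatoblast and yolk sac (0.00657), eye (0.0413), germline (0.0413) and sex-linked (0.0417) lists. Deviations of same-numbered embryos from their group means correlated at -0.0859, 0.175 and 0.264, and only control 2 and knockout 3 correlated best with their own number, so the numbers show no common origin.

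In place of 6 lists, camera called 1 with an estimated correlation, fry 1 and the covariate 10, and 6 to 14 were called without single libraries. Of the lists called with or without the covariate, the medians of 3 changed sign with it: erythroid at -0.31 (camera adjusted p = 2.32e-08), ribosomal proteins at 0.28 (2.96e-13) and oxidative phosphorylation at 0.031 (0.0879). It also gained the heart (0.23, camera adjusted p = 0.000875), eye (-0.28, 0.0384), integrated stress response (0.17, 0.00763) and immediate early (0.23, 0.000256) lists and lost the cell cycle list. These changes rest mostly on knockout 2, the only knockout with a share of reads outside genes within the control range. For repeats, of which edgeR called 0, the covariate gave 7 higher and 7 lower, the fit without knockouts 1 and 3, again with 1 knockout library, gave 3 higher and 4 lower, and DESeq2 gave 2 higher. Without single libraries 0 to 542 were higher, 0 to 2 lower and 0 to 10 groups were called, all of these without knockout 2. The repeat share, lower by 1.87 points in knockouts, was higher by 1.31 points without ribosomal, transfer and small nuclear RNA, as ribosomal RNA itself was lower in the knockouts. The odds ratio near the targeted loci was 1.31 within 5 Mb, 1.22 within 2 Mb and 1.06 to 2.71 without single libraries. Without leukocyte genes it was 1.74 within 10 Mb, 2.23 within 5 Mb and 2.08 within 2 Mb. Fisher's exact p was above 0.05 in each. The leukocyte genes left out were all called ones, so leaving them out does not test their part.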

Other observations

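The genes named in this part were chosen after their values were seen, as were the tests of adult blood in the controls, of blood cells in general and of a single library, and the covariate of reads outside genes. Of 4 tested chains of the receptors for GM-CSF and interleukin 3, 3 rose in embryos whose macrophage genes fell, while Il3ra at 0.89 did not pass the test (edgeR adjusted p = 0.0801). Besides Csf2rb and Csf2rb2, Csf2ra rose from 4.26 ± 0.637 to 8.63 ± 1.76 CPM (SD, n = 3), a log2 fold change of 1.02 with an edgeR adjusted p of 0.0372, though it was called in only 1 of 6 leave-one-out fits, that without knockout 2 (edgeR adjusted p up to 0.19 in the others). Genes of blood progenitors did not pass the test: Kit was at 0.23, Cd34 at -0.19, Myb at -0.56, Itga2b at -0.10 and Runx1 at -0.44, with edgeR adjusted p-values from 0.119 to 0.753. Further macrophage genes had no count in any knockout, with Ctss at least 71.0-fold lower, Fcrls at least 59.6-fold and the microglial receptor Trem2 at least 15.8-fold lower, against 3 counts over the group. Trem2 was lost without control 1 or control 2 (edgeR adjusted p up to 0.0897).

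Single genes with roles in meiosis or the germline rose, although the list fixed for the germline was not called (camera adjusted p = 0.109). The meiotic cohesin gene Stag3 went from 4.16 ± 0.701 to 8.79 ± 1.53 CPM, Rnf17 from 6.93 ± 1.81 to 17.6 ± 3.56 CPM and Zcwpw1 from 10.2 ± 0.839 to 19.3 ± 2.53 CPM (SD, n = 3), with edgeR adjusted p-values of 0.0262, 0.0148 and 0.00947. The predicted gene Gm5801 went from 6 counts over the controls to 39, 63 and 50 counts in the knockouts, at 4.66 ± 0.42 (SE) with an edgeR adjusted p of 0.00083, and was called with any library left out. Gli1 and Ptch1, targets and readouts of Hedgehog signalling, rose by 0.69 and 0.40, and the endothelial gene Vwf by 0.89, with edgeR adjusted p-values of 0.0188, 0.0445 and 0.0175. Zcwpw1 was lost without control 1 or control 2, Rnf17 without control 1 or control 3, Gli1 and Vwf without control 1, control 2 or knockout 3, and Stag3 and Ptch1 without control 1, control 2, control 3 or knockout 3 (edgeR adjusted p up to 0.211).

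The fall of macrophage genes was weighed against 3 technical explanations, of which scaling was excluded, since the list median was at most -3.47 under any other scaling. A general lack of blood cells was taken to lower the erythroid and endothelial lists as well. Their medians were 0.0935 and 0.27, and the lowest fold of the 25 erythroid genes was -0.62. This argues against a loss of erythroid cells as large as the fall of macrophage genes. With reads outside genes as a covariate the erythroid median was -0.31, but that fit rests mostly on knockout 2. Against the control mean knockout 2 was at -0.34, and knockouts 1 and 3 were at 0.31 and 0.24. The embryos thus differed in sign, and a smaller loss is not excluded. Erythroid genes do not show what became of other blood lineages. Adult blood or decidua in the controls stays open, since only 4 of 31 genes of other adult white blood cells had enough counts for the test and went both ways, with a median of 0.636 but Cd79b at -0.96, and S100a8, too low for the test, had 0.82, 0.17 and 0.64 CPM in controls against 0.04, 0.04 and 0.03 in knockouts. Other values lean against it, with H2-Ab1 at 1.24 and Cxcr2 at 0.49, Cd74 at no more than 0.14 CPM, the decidual gene Prl8a2 at no more than 0.034 CPM and Gzma, Gzmb, Prf1 and Ms4a1 at 0 in the controls, where Csf1r had 11.5 CPM, but genes so near 0 do not exclude it, nor do the 5 tested decidual genes (median 0.0529), as Des and Hand2 among them had 29.3 to 46.7 CPM in every library, a baseline that would hide a small share. Adult globin genes gave almost no counts in the controls, with Hbb-b1 at no more than 0.035 CPM and Hbb-b2 and Hba-a1 at 0. Reads shared by gene copies were not counted, so these genes do not decide on adult blood either. Knockout embryos may also hold fewer macrophages, or macrophages that lack these macrophage transcripts, which was not tested and would need cells to be counted.

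The higher reading of hypoxia and glycolysis genes rested mostly on 1 library, with a list median of 0.237 without knockout 2 against 0.77 with it. The median of 1.27 with the covariate also rests mostly on knockout 2. A difference in how long that embryo went without oxygen, in life or during collection, could account for that part. The genotype remains open for the rest, since knockout 3 was also above the controls at 0.41 and knockout 1 at 0.09 was within their range. Vegfa, the only called gene of the list, had 84.9, 128 and 131 CPM in knockouts 1, 2 and 3 against 33.2 to 49.2 CPM in the controls. The groups were fully apart for all 227 called genes, so this separation came with the call and adds nothing on the genotype.

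The other splits of the 6 libraries number 10 with the real one, which cannot give a share under 0.05. The real split called 227 genes and the highest other 1, so that 1 of 10 gave as many. For gene lists the real split called 6 and the highest other 17, with all 10 giving as many, which points to sets of genes that vary together between embryos. For chromosomes the real split called 0 and the highest other 1, and a count of 0 is reached by all 10 by construction.

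The retroviral sequence MuLV-int had 97.5, 111 and 114 CPM in controls and 141, 1.37 and 75.1 in knockouts. The simple repeat (A)n had 683, 738 and 728 CPM in controls and 266, 257 and 661 in knockouts. The retroviral repeats RMER17A, RMER17A-int and ETnERV3-int stood at 0.96, 1.25 and 1.17 on the log2 scale, each with every knockout above every control and an edgeR adjusted p of 0.28. With the covariate edgeR called RMER17A (1.18, adjusted p = 2.45e-07) and RMER17A-int (1.66, 0.00188), and all 3 were called with knockout 2 as the only knockout, where the spread comes from the controls (edgeR adjusted p up to 0.00663).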
